A study of Homo sapiens with 12 samples.

How the data were processed

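The count table lists 37037 genes with at least 1 count in 12 libraries, 4 per cell line, and no column was left unused. The submitters' notes name STAR for alignment to GRCh38, FastQC for read quality and HTSeq for counting, without versions. The gene annotation and the strand setting of the counting are not given in the sources used here. The values are whole numbers and were read as raw counts per gene. Genome positions come from GENCODE release 29 for GRCh38, matched by Ensembl gene ID without version, which placed 36086 IDs (97.4%). Of all IDs, 50.7% carried the same version as that release, so the positions come from another release than the one used for counting for a large part of the genes. Where a symbol stood for more than 1 ID, the ID with the largest total count was used. There were 596 IDs beyond the first of their symbol. Genes with near-identical copies, such as the histone genes, and genes that overlap a neighbour on the opposite strand have uncertain counts, because the handling of shared reads and strand is not given in the sources used here.

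CPM, the normalised read count scaled to a common library size, are edgeR values (cpm function) computed with library sizes scaled by the trimmed mean of M values (TMM). Means and standard deviations (SD) are over the 4 libraries of a line. Genes were kept for testing by edgeR's filterByExpr with the cell line as the group, which left 16037 genes. Differences are log2 ratios from edgeR's quasi-likelihood fit with robust dispersions, tested two-sided, and p values were adjusted by Benjamini-Hochberg over the 16037 genes of a comparison with a threshold of 0.05. Standard errors (SE) of log2 differences were derived from the absolute log2 difference and the square root of the F statistic. Log2 CPM values for gene lists used a prior count of 2.

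Where a line had no count for a gene, the ratio to the other line is given as a lower bound that replaces the total of the line without counts by 3 counts. Where it had 1 to 3 counts in total, the ratio is given with its 95% interval from the counts. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

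The 3 comparisons between cell lines, the panel of genes and 29 gene lists were chosen before the data were examined. The lists are fatty acid synthesis, lipogenic regulators, cholesterol synthesis, fatty acid oxidation, pro-survival and pro-apoptotic members of the BCL2 family, BET proteins and elongation factors, histone genes, MYC and ribosome biogenesis, cell division, DNA replication, cell cycle inhibitors, receptor tyrosine kinases, the ERBB2 amplicon, NF-kB and cytokines, interferon response, immediate early genes, amino acid stress response, autophagy and lysosome, luminal, basal, ovarian and Müllerian, epithelial, mesenchymal, fibroblast, leukocyte and endothelial markers, ribosomal protein genes, and mitochondrially encoded genes. Each list was tested against all other tested genes with limma's camera at a preset correlation between genes of 0.01, and p values were adjusted by Benjamini-Hochberg over the 29 lists of a comparison. The same test was repeated with a correlation estimated from the data. In simulated counts, camera found all 3 of 3 changed lists of 20 genes among 100 lists in each comparison and called 0 unchanged lists. The simulated genes were independent of each other, and all members of a changed list moved the same way. In the data the estimated correlation within a list reached 0.936, so the simulation does not measure false list calls there. Of the 45 symbols in the histone list, 21 matched the table.

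The libraries held 16773183 to 24265230 counts, and the TMM factors ranged from 0.909 to 1.08. In counts simulated with the fitted dispersions for 16037 genes, 200 of them changed per comparison and no pairing of libraries, edgeR recovered 13.1% of 2-fold and 59.3% of 4-fold changes for BT474 against HCC1954. The recovered shares were 16.9% and 76.1% for BT474 against SKOV3, and 16.4% and 64.4% for HCC1954 against SKOV3. With few changed genes the adjustment is stricter than in the data, where more than 50% of genes passed, so these shares do not carry over to the data. A difference that did not pass is still not evidence that a gene was equal. The shares of false calls were 4.35%, 5.97% and 5.00%.

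All 12 libraries are labelled as treated with JQ1, and neither the labels nor the table's header names an untreated library. No contrast of JQ1 against a control was therefore computed, and no library is called a control. The protocol speaks of biological duplicates, while 4 libraries per line are present, so some libraries of a line may share a culture and the 4 values of a line may not be independent. Whether libraries with the same number in different lines belong together was checked by the correlation, across genes, of their deviations from the line mean. Over 12 pairs of libraries with the same number the correlations were 0.393 to 0.482, and the own number gave the best match in 3 of the 12 pairs. In each of the 12 the best match was a library of the same pair of numbers, 1 or 2 for libraries 1 and 2, and 3 or 4 for libraries 3 and 4. The main fit has no term for the library number, so its p values and SEs treat the 4 libraries of a line as independent. A fit with the number as a block was computed as an alternative. That block gives each number the same shift in every line, so it cannot follow genes whose libraries part differently between lines. No fit took the pairs of libraries as its units.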

Results

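Messenger RNA was measured in 3 human cancer cell lines with high HER2: BT474 and HCC1954, both from HER2-positive breast carcinoma, and SKOV3, an ovarian carcinoma line with amplified ERBB2 that the labels list under breast tissue. The series concerns BET inhibition, MCL1 targeting and fatty acid synthesis. All libraries are labelled as cells treated with JQ1, an inhibitor of the BET bromodomain proteins, at 1 µM for 24 h. RNA was captured with oligo(dT), and paired-end reads were sequenced and counted per gene. There are 4 libraries per line, with total counts of 16773183 to 24265230, and 16037 genes were tested. The labels do not say which libraries, if any, were untreated, so only differences between the cell lines were tested. Each mean below averages the 4 libraries of a line, and its SD includes any difference between cultures or treatments within that line.

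FASN (ENSG00000169710.6, chromosome 17, 82078333 to 82098332), which encodes fatty acid synthase, was most abundant in BT474, where it reached 4516 ± 987 CPM (SD, n = 4), against 853 ± 20.2 in HCC1954 and 488 ± 159.9 in SKOV3. MCL1 (ENSG00000143384.11, chromosome 1, 150574551 to 150579738), which encodes a pro-survival protein of the BCL2 family, was abundant in each line, with 643 ± 276, 661 ± 209.7 and 435 ± 137 CPM in the same order. ERBB2 (ENSG00000141736.12, chromosome 17, 39687914 to 39730426), which encodes HER2, had 8402 ± 817, 8581 ± 446 and 6720 ± 366 CPM.

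Between BT474 and HCC1954, the breast lines, BT474 had the higher expression of FASN and ACACA, while HCC1954 had more KRT17, a basal keratin gene. ACACA, which makes malonyl-CoA for fatty acid synthesis, was 181 ± 39.2 CPM in HCC1954 and 1253 ± 319.5 in BT474 (log2 difference -2.79, SE 0.22, adjusted p = 7.41e-07). FASN was lower in HCC1954 in edgeR's quasi-likelihood test (-2.40, SE 0.24, adjusted p = 5.54e-06). SCD, the desaturase, was 1509 ± 264 CPM against 2304 ± 666 (-0.61, SE 0.23, adjusted p = 0.0398), and ACLY was 389.8 ± 6.26 against 516 ± 34.00 (-0.40, SE 0.11, adjusted p = 0.00686). The SCD call was lost when any of 6 libraries was left out. The transcription factor gene SREBF1 did not pass (adjusted p = 0.397). In total 8641 of 16037 genes (53.9%) passed an adjusted p of 0.05, with 4273 higher and 4368 lower in HCC1954, and 6195 of them differed more than 2-fold. The 4 values of each line were fully separated for 49.2% of genes, against 2.86% by chance if libraries were independent. The libraries of a line fell into pairs, so that chance value is too low.

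The desaturase genes FADS1 and FADS2 were far lower in HCC1954: FADS2 had 15.2 CPM in HCC1954 and 1085 in BT474 (log2 -6.16, SE 0.45, adjusted p = 3.50e-07), and FADS1 had 6.54 and 134 (-4.35, SE 0.21, adjusted p = 9.46e-09). ACSS2, which makes acetyl-CoA from acetate, was lower too (38.6 against 232 CPM, -2.59, SE 0.22, adjusted p = 1.06e-06). ACSL4, a long-chain acyl-CoA synthetase gene, went the other way, with 72.4 CPM in HCC1954 and 2.77 in BT474 (4.71, SE 0.39, adjusted p = 9.86e-07). ELOVL6 and ME1 were also higher in HCC1954. Of the 24 tested genes in the list, 5 were higher and 11 lower, and the list did not pass against other genes (adjusted p = 0.108; 0.270 with an estimated correlation). Among lipogenic regulators, 4 of 20 were higher and 4 lower, including SREBF2 at 123 against 423 CPM; adjusted over the list alone, 3 were lower. The median of that list was below 0 and the mean above 0, and it did not pass (adjusted p = 0.753). Cholesterol synthesis genes split into 5 higher and 7 lower of 23 (adjusted p = 0.497), and fatty acid oxidation genes into 4 and 6 of 20 (adjusted p = 0.553). Within the latter, ECI2 was almost without counts in HCC1954 (0.0647 CPM against 83.8), and CPT1A had 48.00 against 212 CPM.

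**Figure D1:**
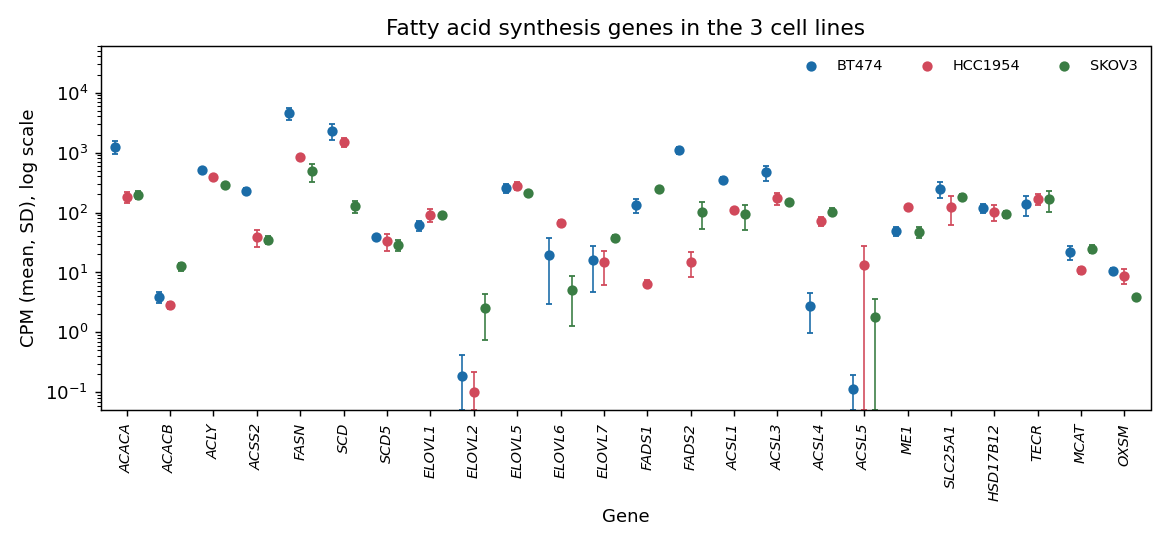
Expression of the tested fatty acid synthesis genes (horizontal axis) in CPM on a log scale (vertical axis); points are means of 4 libraries of a cell line and lines are the SD, cut short at the bottom where it exceeds the mean. FADS2 was at 1085 CPM in BT474 and 15.2 in HCC1954, and SCD was at 126 in SKOV3.

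Among apoptosis genes, BCL2, BCL2L1 and BCL2L11 were lower in HCC1954 than in BT474, while MCL1 did not pass. BCL2 had 0.259 CPM in HCC1954 and 15.5 ± 12.9 in BT474 (log2 -5.86, SE 0.85, adjusted p = 0.000102), and BCL2L1, which encodes BCL-XL, had 66.4 and 128 (-0.95, SE 0.16, adjusted p = 0.000323). MCL1 had a log2 difference of 0.04, SE 0.34, adjusted p = 0.934. BCL2L11, which encodes the pro-apoptotic BIM, was lower in HCC1954 (25.2 against 97.4 CPM, -1.95, SE 0.42, adjusted p = 0.00175), as was BBC3, which encodes PUMA (1.98 against 26.04 CPM). PMAIP1, which encodes NOXA, a partner of MCL1, was higher (20.4 against 10.2 CPM, 1.00, SE 0.30, adjusted p = 0.0125). Most of that difference lay in libraries 3 and 4 (24.9 and 26.4 CPM in HCC1954 against 7.23 and 7.46 in BT474). Libraries 1 and 2 were closer (15.9 and 14.6 CPM against 13.1 and 13.1). Of 4 tested pro-survival genes 2 were lower (adjusted p = 0.412), and of 11 pro-apoptotic genes 3 were higher and 4 lower (adjusted p = 0.696). The elongation factor gene ELL2 was higher in HCC1954 (192 against 11.5 CPM). Over BET proteins and elongation factors, 2 of 16 genes were higher and 5 lower (adjusted p = 0.444). HEXIM1 and CDKN1A did not pass (adjusted p = 0.190 and 0.152). With the library number as a block, HEXIM1 was lower in HCC1954 (log2 -0.74, adjusted p = 0.0110) and CDKN1A higher (1.69, adjusted p = 3.42e-05). For HEXIM1, libraries 1 and 2 were close (55.4 and 54.7 CPM against 65.6 and 57.3 in BT474). Libraries 3 and 4 were far apart (138 and 151 CPM against 333 and 354). The block cannot follow such a gene, so its HEXIM1 call is not a difference shared by all libraries.

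Most luminal markers were lower and most basal markers higher in HCC1954, and both list calls were lost with an estimated correlation. TFF3, a secreted trefoil factor, had 0.100 CPM against 244 ± 104 in BT474 (log2 -11.18, SE 0.45, adjusted p = 2.97e-09), and the progesterone receptor gene PGR had 0.0327 against 213. KRT17, a basal keratin, had 2459 ± 228 CPM in HCC1954 and 0.421 in BT474 (log2 12.50, SE 0.72, adjusted p = 5.38e-08), and KRT15 had 1864 ± 552 against 29.8. Of 16 luminal markers 14 were lower and 1, KRT18, was higher (adjusted p = 1.49e-06; 0.0918 with an estimated correlation). Of 17 basal markers 15 were higher and 1 was lower (adjusted p = 1.49e-06; 0.270 with an estimated correlation). Mesenchymal markers moved both ways, with TAGLN at 122 against 1.98 CPM and TWIST1 at 0.352 against 14.5, and 11 of 18 were higher and 4 lower (adjusted p = 0.0188; 0.409 with an estimated correlation). Epithelial markers mostly did not pass (5 higher and 2 lower of 19, adjusted p = 0.497). Markers named after ovarian and Müllerian tissue were higher in 8 of 11 cases (adjusted p = 7.90e-05; 0.197 with an estimated correlation), among them KLK6 at 495 ± 213 CPM against 0.0546 and MUC16 at 31.05 against 0.0382; adjusted over the list alone, 8 were higher and 1 lower.

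More genes of the NF-kB and interferon lists were higher than lower in HCC1954, and both list calls were lost with an estimated correlation. PLAUR, the urokinase receptor gene, had 49.4 CPM against 0.774 (log2 5.99, SE 0.24, adjusted p = 2.67e-09), CXCL8 had 17.9 against 0.344, and IRF1 had 60.5 against 7.37. The NF-kB list had 9 of 14 genes higher and none lower at that threshold (adjusted p = 0.000405; 0.137 with an estimated correlation). The interferon list had 15 higher and 2 lower of 27 (adjusted p = 0.00382; 0.595 with an estimated correlation), and 16 higher when adjusted over the list alone. MX2 was lower, at 0.239 CPM against 42.5. Cell division genes such as NUSAP1 (153 against 27.1 CPM) were higher in 10 of 20 cases (adjusted p = 0.00371; 0.448 with an estimated correlation). DNA replication genes such as GINS2 (104 against 18.8 CPM) were higher in 7 and lower in 1 of 24 (adjusted p = 0.0195; 0.794 with an estimated correlation). The DNA replication call was lost without library 3 or 4 of BT474 (0.0981 and 0.102), and both the DNA replication and the interferon list varied more between libraries of a line than random lists of like expression (median SD on the log2 scale 0.592 and 0.834). Ribosomal protein genes were higher in 18 of 25 cases (adjusted p = 0.00205; 0.794 with an estimated correlation) and lower in 1, RPL19, which lies near ERBB2 and had 898 CPM against 6549.

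Between the breast lines ERBB2 did not differ beyond the spread of the libraries (log2 0.03, SE 0.13, adjusted p = 0.863), while ERBB3 was lower in HCC1954 (52.8 ± 12.2 against 233 ± 60.9 CPM, -2.14, SE 0.22, adjusted p = 7.12e-06) and EGFR higher (181 ± 38.8 against 84.3 ± 27.03 CPM, 1.11, SE 0.26, adjusted p = 0.00302). MET was at 503 CPM against 49.6, and RET at 0.607 against 182. FOSL1, a gene downstream of ERK signalling, had 12.5 ± 2.58 against 0.462 ± 0.282 CPM (4.71, SE 0.39, adjusted p = 1.07e-06), and CDKN2A had 117 against 5.19. MYC did not pass (adjusted p = 0.230), although libraries 3 and 4 were far apart (49.3 and 40.2 CPM in HCC1954 against 5.86 and 6.07 in BT474). Libraries 1 and 2 were closer (51.8 and 56.4 CPM against 51.1 and 45.3). The receptor tyrosine kinase list had 5 of 20 genes higher and 8 lower (adjusted p = 0.444), and the ERBB2 amplicon list 4 higher and 4 lower of 10, with a median above 0 and a mean and test direction below 0 (adjusted p = 0.688).

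The other lists did not pass between BT474 and HCC1954. MYC and ribosome biogenesis genes had 11 higher and 7 lower of 32 (adjusted p = 0.380). Histone genes had 3 higher of 21 (adjusted p = 0.688), and 1 when adjusted over the list alone. Cell cycle inhibitors had 3 higher and 3 lower of 11, with CDKN1B at 19.4 against 107 CPM. Immediate early genes had 8 higher and 4 lower of 20, with DUSP4 at 100.1 against 659.6 CPM. Amino acid stress genes had 8 and 5 of 19, and autophagy and lysosome genes 9 and 5 of 25. Fibroblast markers had 3 higher and 2 lower of 7, leukocyte markers 2 higher of 5, and endothelial markers 3 higher of 4, such as PECAM1 at 12.7 against 0.0356 CPM. The adjusted p values of these lists from cell cycle inhibitors to endothelial markers were 0.688, 0.326, 0.497, 0.497, 0.553, 0.444 and 0.326. None of the 13 mitochondrially encoded genes passed in any of the 3 comparisons (adjusted p = 0.444, 0.437 and 0.984 for the lists).

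Among genes with large differences that stood outside the lists, the metalloreductase gene STEAP4 had 607 ± 124 CPM in HCC1954 and no counts in BT474, at least 15563-fold higher. The protease gene KLK5 had 1025 ± 81.8 CPM against 2 counts in total in BT474, a ratio of 39411 (95% interval 10910 to 325426). In the other direction, the calcium pump gene ATP2A3 had 0.0783 CPM against 1154 ± 515 in BT474 (log2 -13.77, adjusted p = 9.27e-09). The lipoxygenase gene ALOX15B had no counts in HCC1954 and 80.02 ± 68.2 CPM in BT474, at least 2437-fold lower, and PTPRN2 had no counts against 51.7 ± 11.05 CPM, at least 1576-fold lower.

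SKOV3 had lower FASN, SCD and FOXA1 than BT474, and higher VIM. SCD had 126 ± 28.6 CPM in SKOV3 and 2304 ± 666 in BT474 (log2 -4.19, SE 0.26, adjusted p = 6.37e-08), and SREBF1 had 25.04 ± 9.16 and 295 ± 114 (-3.56, SE 0.33, adjusted p = 1.73e-06). FASN and ACACA were lower in SKOV3 in edgeR's test (log2 -3.21, SE 0.25, adjusted p = 4.50e-07 and -2.66, SE 0.22, adjusted p = 7.52e-07), and ACLY was lower by a smaller amount (-0.83, adjusted p = 3.37e-05). VIM, which encodes vimentin, had 3827 ± 1525 CPM against 29.4 ± 6.23 (7.03, SE 0.35, adjusted p = 9.39e-09), and FOXA1, a luminal transcription factor gene, had 4.19 against 523 ± 74.1 (-6.96, SE 0.17, adjusted p = 7.86e-11). In total 9423 of 16037 genes (58.8%) passed, with 4782 higher and 4641 lower in SKOV3, and 6984 differed more than 2-fold. The values of the lines were fully separated for 54.6% of genes.

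The fatty acid synthesis list had 6 of 24 genes higher and 10 lower in SKOV3 (7 and 10 when adjusted over the list alone) and did not pass (adjusted p = 0.185). FADS1 (247 against 134 CPM) and ACSL4 (104 against 2.77 CPM) were among those higher in SKOV3. Cholesterol synthesis genes were lower in 14 of 23 cases and higher in 2 (adjusted p = 0.00191; 0.481 with an estimated correlation). EBP, a sterol isomerase gene, had 1.74 CPM against 67.5 (log2 -5.26, SE 0.47, adjusted p = 1.49e-06), and DHCR7 had 61.05 against 276 (-2.18, SE 0.13, adjusted p = 3.25e-08). SC5D was higher (166 against 32.3 CPM). Lipogenic regulators had 4 higher, including PPARG, and 9 lower, including INSIG1 (32.4 against 173 CPM), of 20 (adjusted p = 0.335).

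Luminal markers were lower in 14 of 16 cases in SKOV3, and this call held with an estimated correlation (adjusted p = 6.09e-08; 0.0466 with an estimated correlation; 0.0462 with that and the library number as a block). GATA3, a luminal transcription factor gene, had 1.20 CPM against 242. ESR1, the estrogen receptor gene, did not pass (72.9 against 36.7 CPM). Of 19 epithelial markers 18 were lower and 1 was higher (adjusted p = 2.99e-07; 0.0928 with an estimated correlation): CDH1, which encodes E-cadherin, had 7.37 CPM against 1333, and RAB25 had 0.137 against 61.2 (log2 -8.76, adjusted p = 6.71e-10). The exception was CLDN1, with 89.6 CPM in SKOV3 against 2 counts in BT474, a ratio of 3446 (95% interval 954 to 28458). Mesenchymal markers were higher in 14 and lower in 1 of 18 (adjusted p = 1.39e-06; 0.0774 with an estimated correlation; 0.0417 with that and the library number as a block), with FN1 at 686 against 3.31 CPM. Basal markers were higher in 10 and lower in 3 of 17 (adjusted p = 0.0302; 0.636 with an estimated correlation; 0.0709 with the library number as a block). CAV1 had 930.0 ± 216 CPM against 0.562 (log2 10.70, adjusted p = 1.20e-07) and KRT15 was lower (2.05 against 29.8 CPM).

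Ovarian and Müllerian markers were higher in 9 of 11 cases in SKOV3 (adjusted p = 0.000176; 0.126 with an estimated correlation). PAX8, a transcription factor gene of the Müllerian tract, had 241 ± 78.3 CPM against 2 counts in BT474, a ratio of 9282 (95% interval 2570 to 76648). SOX17 had 101 CPM and no counts in BT474 and HCC1954, and LHX1 had 101 CPM against 0.202 in BT474. NF-kB genes were higher in 12 of 14 cases (adjusted p = 0.000219; 0.0812 with an estimated correlation; 0.0462 with that and the library number as a block), or 13 when adjusted over the list alone, with LIF at 10.4 against 0.0132 CPM. Interferon genes were higher in 17 and lower in 4 of 27 (adjusted p = 0.0302; 0.636 with an estimated correlation), with ISG15 at 12.9 against 0.802 CPM. The histone list did not pass in the main test but passed with the library number as a block (adjusted p = 0.116 without, 0.00505 with it, 0.526 with the block and an estimated correlation), and 11 of 21 genes were lower, such as H1F0 at 12.5 against 551 CPM.

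MCL1 did not pass between SKOV3 and BT474 (log2 -0.56, SE 0.34, adjusted p = 0.169) but passed with the library number as a block (0.00396). BCL2 was lower in SKOV3 (4.52 against 15.5 CPM, -1.77, adjusted p = 0.0395; lost when any of 4 libraries was left out), BCL2L1 did not pass (adjusted p = 0.393), BCL2L11 was lower (25.2 ± 14.3 against 97.4 ± 43.1 CPM, -1.95, adjusted p = 0.00150) and PMAIP1 higher (37.6 against 10.2 CPM, 1.88, adjusted p = 0.000177). The BET protein and elongation factor list, the DNA replication list and the receptor tyrosine kinase list did not pass (adjusted p = 0.993, 0.958 and 0.788), and in each the median, the mean and the test direction differed in sign. HEXIM1 and CDKN1A did not pass (adjusted p = 0.280 and 0.130). With the block, HEXIM1 was higher in SKOV3 (log2 1.10, adjusted p = 0.000899) and CDKN1A lower (-1.53, adjusted p = 6.58e-05). MYC did not pass (0.801), but its libraries crossed. Libraries 1 and 2 were lower in SKOV3 (27.3 and 26.2 CPM against 51.1 and 45.3). Libraries 3 and 4 were higher in SKOV3 (36.5 and 33.3 CPM against 5.86 and 6.07). ERBB3 was lower (1.98 ± 0.348 against 233 ± 60.9 CPM, -6.88, SE 0.28, adjusted p = 2.09e-09), and EGFR (1.40, adjusted p = 0.000518) and FOSL1 (6.25, SE 0.41, adjusted p = 1.02e-07) were higher. AXL, a receptor kinase gene, had 503 CPM against 0.306. ERBB2 was slightly lower in SKOV3 (log2 -0.32, SE 0.13, adjusted p = 0.0474), and the call was lost with the block (0.0758) and with several other settings.

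Large differences outside the lists included the G protein subunit gene GNG11 (182 ± 21.5 CPM, at least 4660-fold higher), the growth factor gene FGF2 (129.8 ± 72.8 CPM, at least 3327-fold higher) and the cyclin gene CCNA1 (106 ± 12.8 CPM, at least 2720-fold higher), each without counts in BT474. PRLR, the prolactin receptor gene, had 1 count in SKOV3 and 388 ± 198 CPM in BT474, a ratio of 31604 (95% interval 5672 to 1248310). SOX11 also had 1 count in SKOV3, against 477 ± 339 CPM, a ratio of 38871 (95% interval 6976 to 1535300), and ALDH3B2 had 3 counts against 602 ± 316 CPM, a ratio of 16349 (95% interval 5594 to 79275).

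SKOV3 and HCC1954 shared low ACACA but parted in SCD, SREBF1 and GRHL2. ACACA did not pass between them (log2 0.14, SE 0.21, adjusted p = 0.607). SCD had 126 ± 28.6 CPM in SKOV3 and 1509 ± 264 in HCC1954 (log2 -3.58, SE 0.25, adjusted p = 2.55e-07), SREBF1 had 25.04 ± 9.16 and 238 ± 30.6 (-3.25, SE 0.32, adjusted p = 4.33e-06), and FASN and ACLY were lower in SKOV3 by less (-0.81, adjusted p = 0.0107 and -0.42, adjusted p = 0.00526). GRHL2, an epithelial transcription factor gene, had 0.254 CPM against 142 (-9.07, SE 0.35, adjusted p = 1.90e-09). In total 8768 of 16037 genes (54.7%) passed, with 4500 higher and 4268 lower in SKOV3, and 6308 differed more than 2-fold. The values of the lines were fully separated for 55.7% of genes.

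The fatty acid synthesis list had 6 of 24 genes higher and 8 lower in SKOV3 and did not pass (adjusted p = 0.883). Its median log2 difference was -0.12 and its mean 0.14. FADS1 (247 against 6.54 CPM) and FADS2 (102 against 15.2 CPM) were higher in SKOV3. Cholesterol synthesis genes were lower in 14 and higher in 2 of 23 (adjusted p = 0.0110; 0.804 with an estimated correlation), with EBP at 1.74 against 151 CPM. Epithelial markers were lower in 17 of 19 cases (adjusted p = 7.12e-10; 0.188 with an estimated correlation), with RAB25 and CLDN4 at log2 -9.64 and -6.36. Mesenchymal markers were higher in 11 and lower in 2 of 18 (adjusted p = 0.00678; 0.555 with an estimated correlation), with FBN1, which encodes fibrillin, at 195 against 0.248 CPM and VIM at log2 5.42. These were the only 3 of 29 lists that passed in the main test of this comparison; without the low count filter 8 more passed. Histone, ribosome biogenesis, cell division and DNA replication lists tied at an adjusted p of 0.0531, each with more genes lower than higher in SKOV3, and passed with the library number as a block (histone genes 0.00138, the other lists 0.0426), though not with the block and an estimated correlation (histone genes 0.748, the other lists 0.814). Luminal and basal markers did not pass in the main test (0.0735 and 0.0927), although KRT15 was far lower in SKOV3 (log2 -9.81) and CA12 (log2 7.57) far higher. The NF-kB list had a median above 0 and a mean and test direction below 0 (0.948).

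BCL2 was higher in SKOV3 than in HCC1954 (log2 4.09, SE 0.81, adjusted p = 0.000985), as were BCL2L1 (0.79, adjusted p = 0.00124) and PMAIP1 (0.88, adjusted p = 0.0224). MCL1 was not (-0.60, SE 0.34, adjusted p = 0.149), except with the library number as a block, when it was lower in SKOV3 (0.00158). BCL2L11 had a mean of 25.2 CPM in both lines (adjusted p = 1.00), but its libraries crossed. Libraries 1 and 2 were lower in SKOV3 (12.7 and 13.2 CPM against 22.2 and 21.1 in HCC1954). Libraries 3 and 4 were higher in SKOV3 (35.8 and 39.3 CPM against 29.01 and 28.5). The equal means therefore do not show equal expression. HEXIM1 (1.84, adjusted p = 0.0280) was higher in SKOV3, and CDKN1A was lower (-2.90, adjusted p = 0.0110). The calls of PMAIP1 and HEXIM1 were each lost when any of 4 libraries was left out. MYC and EGFR did not pass (adjusted p = 0.341 and 0.342). FOSL1 was higher (1.55, adjusted p = 0.00135) and ERBB3 lower (-4.74, adjusted p = 2.71e-08). ERBB2 was lower by a small amount (-0.35, SE 0.13, adjusted p = 0.0347), a call lost with the block (0.0571). CDKN2A had 0.0975 CPM against 117 in HCC1954, and AXL had 503 against 6.72.

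Outside the lists, the guanine deaminase gene GDA had 197 ± 19.7 CPM in SKOV3 and no counts in HCC1954, at least 5988-fold higher, and HOXB6 had 109.7 ± 27.6 CPM, at least 3340-fold higher. C1orf186 had 101 ± 29.4 CPM, at least 3087-fold higher. KLK5 had no counts in SKOV3, at least 27842-fold lower than in HCC1954, and the calcium channel gene TRPV6 had none against 117 ± 28.6 CPM, at least 3181-fold lower. From the ovarian and Müllerian list, KLK6 had 1 count in SKOV3, a ratio of 40364 (95% interval 7245 to 1594290) to HCC1954.

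Around ERBB2 on chromosome 17 the lines shared high ERBB2 but not its neighbours. MED1, a mediator subunit gene, had 1496 ± 277 CPM in BT474, 64.02 in HCC1954 and 153 in SKOV3 (log2 -4.55, SE 0.18, adjusted p = 2.22e-09 between HCC1954 and BT474). On the same side, CDK12 had 658, 120.2 and 155 CPM. GRB7, an adaptor gene next to ERBB2, had 287, 992 ± 91.2 and 35.04 ± 15.8 CPM, and was lower in SKOV3 than in HCC1954 (log2 -4.82, adjusted p = 1.09e-07). STARD3 had 806, 1806 ± 112 and 286 CPM, and ORMDL3 had 667, 2071 and 69.2. PSMD3, a proteasome subunit gene, had 2997 ± 750.1, 381 and 570.4 CPM. PPP1R1B was highest in SKOV3, with 1.59, 7.75 and 763 ± 489.7 CPM. The amplicon list was lower in 9 of 10 genes in SKOV3 against BT474 and higher in 1, MIEN1 (adjusted p = 0.000720; 0.0835 with an estimated correlation), and did not pass between SKOV3 and HCC1954 (adjusted p = 0.211). MIEN1 and PGAP3 overlap ERBB2 on the opposite strand, so reads of ERBB2 can count for them if strand was not used.

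**Figure D2:**
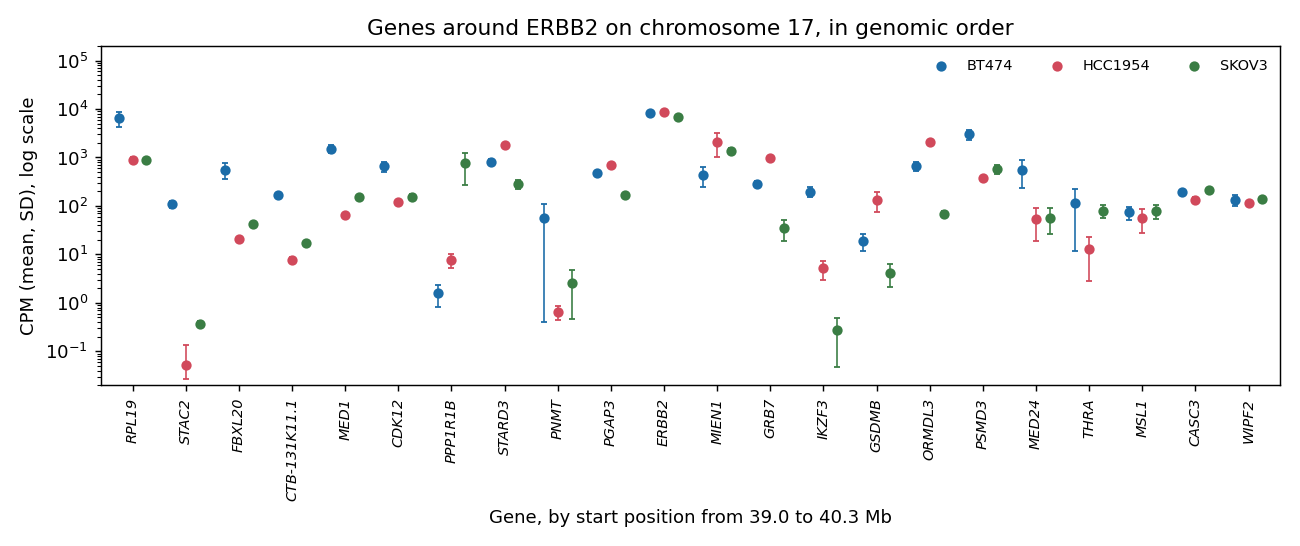
Expression in CPM on a log scale (vertical axis) of genes around ERBB2 on chromosome 17 in genomic order (horizontal axis), for genes with high expression in at least 1 line; points are means of 4 libraries of a cell line and lines are the SD, cut short at the bottom where it exceeds the mean. ERBB2 lay at 8402, 8581 and 6720 CPM, while MED1 ranged from 64.02 to 1496.

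Some genes of the panel varied between the libraries of a line. HEXIM1, whose product restrains the elongation factor P-TEFb, had 65.6, 57.3, 333 and 354 CPM in libraries 1 to 4 of BT474, 55.4, 54.7, 138 and 151 in HCC1954 and 197, 193, 512 and 529 in SKOV3. MCL1 had 389.7, 418, 895 and 869 CPM in BT474, 489, 469.9, 853 and 831 in HCC1954 and 333, 301, 557 and 549 in SKOV3. FASN had 3376, 4035, 5521 and 5132 CPM in BT474, 837, 837, 860.1 and 879 in HCC1954 and 400.1, 306, 617 and 627 in SKOV3. SCD had 1568, 2003, 3104 and 2543 CPM in BT474, 1252, 1316, 1695 and 1775 in HCC1954 and 163, 135, 104 and 103 in SKOV3. MYC had 51.1, 45.3, 5.86 and 6.07 CPM in BT474, 51.8, 56.4, 49.3 and 40.2 in HCC1954 and 27.3, 26.2, 36.5 and 33.3 in SKOV3. BCL2L11 had 55.97, 64.7, 138 and 132 CPM in BT474, 22.2, 21.1, 29.01 and 28.5 in HCC1954 and 12.7, 13.2, 35.8 and 39.3 in SKOV3. These values carry no test of treatment, because the labels do not part the libraries of a line.

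**Figure D3:**
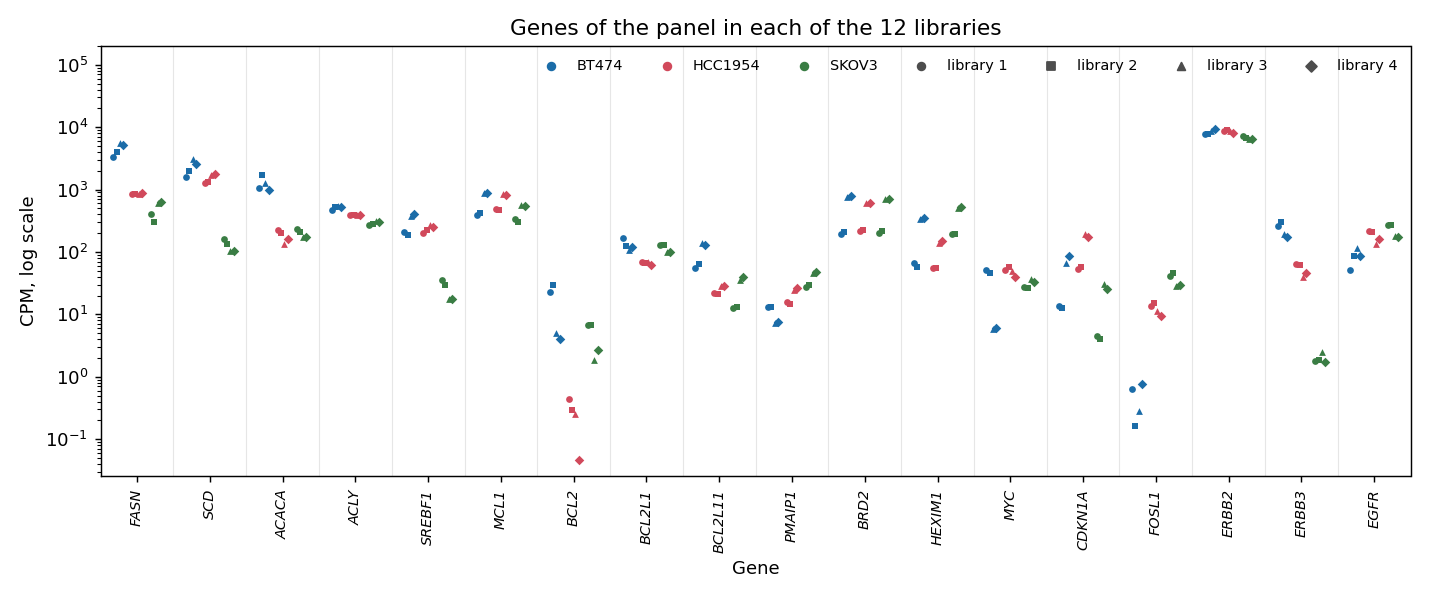
Expression in CPM on a log scale (vertical axis) of 18 genes of the panel (horizontal axis) in each of 12 libraries; colour marks the cell line and each marker is 1 library. CDKN1A had 4.48, 3.98, 30.3 and 25.4 CPM in the libraries of SKOV3, and ERBB2 had 8785, 8961, 8636 and 7941 in those of HCC1954.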

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

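Each test in this part was written down before its own result was seen; the test on gene families was added after the correlation of neighbouring genes was known.

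In each line the 4 libraries were compared for each named gene, the total counts, the mitochondrial share and the share of the most abundant genes. Of these 200 groups of 4 libraries, 10 held a library far from the other 3, all of them groups of named genes. A library was far when the ratio of the gap to the range lay above the critical value of 0.829. Ratios of genes were computed on log2 CPM. By chance about 1 in 20 groups of independent values is flagged, a rate that need not hold for near-zero counts or paired libraries. BCL2L1 in HCC1954 had 61.4 CPM in library 4 against 67.5 to 68.4 in the others (ratio 0.879). CA12 in SKOV3 had 145 CPM in library 3 against 138 to 139 (0.869). PAX8 in HCC1954 had 4.01 CPM in library 3 against 2.63 to 2.73 (0.908). The other 7 groups had a ratio of 1, because only 1 library of the line had a count and the others had 0, among them FOLR1 (0.0526 CPM) and GDA (0.0569 CPM) in BT474, GNG11 (0.0467 CPM) in HCC1954, and KLK6 (0.0414 CPM), PRLR (0.0414 CPM) and SOX11 (0.0609 CPM) in SKOV3. None of these changes a call between lines.

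The libraries of each line fell into pairs, libraries 1 and 2 and libraries 3 and 4. For example, HEXIM1 in SKOV3 had 197, 193, 512 and 529 CPM and CDKN1A in BT474 had 13.8, 12.8, 66.9 and 85.2. After centring genes within a line, the lowest correlation across genes between a library and its closest library was 0.484 and the highest with any further library -0.675, while -0.333 is the value without structure. The pairs remained when each library was thinned to the smallest total (lowest correlation 0.511), when the 500 most abundant genes were left out (0.488) and when trends on transcript length and GC content were removed (0.558), which argues against depth, a few abundant genes, length and GC content as the whole cause. The share of counts from mitochondrially encoded genes ordered the pairs in 3 of 3 lines, so a difference in RNA or cell state marked by that share could belong to the pairs, although the abundant genes themselves are not needed for them.

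A difference between cultures, harvests, preparations or treatments stays open as the source of these pairs, and no biological explanation was tested, because the labels give the same treatment to all 12 libraries. No library was an exact copy of another of its line. Even the most alike libraries, 3 and 4 of SKOV3, differed by a chi-square of 2.71 per degree of freedom. Libraries 1 and 2 differed by 3.95 in HCC1954, 7.93 in SKOV3 and 51.5 in BT474. Across the pairs of SKOV3 the values were 97.04 to 107.7. This check cannot tell separate preparations of the same RNA or culture from separate cultures.

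The number of genes that differed between cell lines was compared with that from the other splits of the same 8 libraries. Of the 35 splits into groups of 4, only 1, the cell lines themselves, gave as many genes in each comparison. The highest number from another split was 632 for BT474 and HCC1954, 355 for BT474 and SKOV3, and 20 for HCC1954 and SKOV3, against 8641, 9423 and 8768 for the lines. In each comparison that was the split of libraries 1 and 2 of both lines from libraries 3 and 4, which follows the pairs described above, and the remaining splits each gave 0. A split that mixes the lines carries their difference in its residual spread, so few genes are expected from it, and these counts are no measure of the error in the comparison of the lines.

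Genes that lie near each other differed alike between the lines. Over genes up to 10 places and at least 50000 bases apart, the mean rank correlation of log2 differences was 0.138 for BT474 and HCC1954, 0.124 for BT474 and SKOV3 and 0.142 for HCC1954 and SKOV3, against at most 0.00957, 0.00926 and 0.0118 in 1000 shuffles of gene positions (permutation p = 0.000999, the smallest that number of shuffles can give). Without chromosome 17 the values were 0.134, 0.120 and 0.144. Neighbours with like symbols do not account for all of this: over protein-coding neighbours whose symbols do not share their first 3 letters, the values were 0.131, 0.124 and 0.133. Related genes with unlike symbols stay among those pairs, so the test cannot exclude a part played by clustered gene families. A difference in chromosome copy number between the lines may contribute, and regulation shared by neighbouring genes stays open; a DNA copy-number measurement is not used here.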

How the results depend on the processing

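The alternatives for the gene lists were chosen after the data were seen; those for genes and counts of genes were planned. The comparisons of JQ1 with a control, and the alternatives that depend on them, were not run, because neither the labels nor the header name a control.

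The counts of differing genes stayed near their main values under DESeq2 (4489 higher and 4703 lower in HCC1954 against BT474), other scaling and the omission of any library (8081 to 8742, 8904 to 9573 and 8159 to 9197 for BT474 and HCC1954, BT474 and SKOV3, and HCC1954 and SKOV3). In the same order they were 10187, 10897 and 10326 with the block, 8964, 10158 and 9188 without the low count filter, and 6391, 6848 and 6458 when at least 10 CPM in 2 libraries was asked for, which tests 11124 genes and not 16037. They fell further when a fold change above 2 was required: to 3896 for BT474 and HCC1954, 4940 for BT474 and SKOV3, and 4047 for HCC1954 and SKOV3. That test asks for more than a difference from 0, which is the cause by construction.

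The fatty acid synthesis list did not pass in the main test (adjusted p = 0.108, 0.185 and 0.883). It passed with fry, which asks whether its genes move one way on balance and not whether they do so more than others (3.91e-07, 1.11e-06 and 0.0259). Over all lists fry gained 36 calls. For SKOV3 against HCC1954 fry's direction was up and camera's down; the mean of the list was above 0 and its median below. Without the low count filter it passed for BT474 and HCC1954 (adjusted p = 0.0142), 1 of 12 list calls gained with that setting; the cause was not tested. The others were histone genes (0.0184), fibroblast markers (0.0105) and ribosomal protein genes (0.00300) in SKOV3 against BT474, and, in SKOV3 against HCC1954, histone genes (0.00291), ribosome biogenesis (0.00426), cell division, DNA replication and luminal markers (0.00387 each), basal and fibroblast markers (0.0102 each) and ovarian and Müllerian markers (0.0319).

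With an estimated correlation 20 list calls were lost, and only the luminal markers in SKOV3 against BT474 held. With the block and an estimated correlation 18 were lost, and in SKOV3 against BT474 the luminal markers (adjusted p = 0.0462), NF-kB (0.0462) and mesenchymal markers (0.0417) held. Leaving out single libraries lost 2 list calls, both of DNA replication in HCC1954 against BT474 (0.0981 without library 3 of BT474 and 0.102 without library 4). It gained 29: in SKOV3 against HCC1954 histone genes (7 cases) and ribosome biogenesis, cell division and DNA replication (5 each), and in SKOV3 against BT474 ribosomal protein genes (5), histone genes (1) and fibroblast markers (1). With the library number as a block, 5 list calls were gained and 1 lost, and among named genes the calls of CDKN1A, HEXIM1, MCL1 and ERBB2 changed as given with each result (MCL1 in SKOV3 against HCC1954, adjusted p = 0.00158); the block changed no other call. ERBB2 in SKOV3 against BT474 was also lost with DESeq2 size factors (adjusted p = 0.0507), upper quartile scaling (0.0515), no low count filter (0.107) and at least 10 CPM in 2 libraries (0.0538), and when any of 9 of the 12 libraries was left out; DESeq2's own test kept it. Leaving out single libraries raised the adjusted p to at most 0.130 for SCD in HCC1954 against BT474 (lost in 6 of 12 cases), 0.145 for BCL2 in SKOV3 against BT474 (4 cases), and, in SKOV3 against HCC1954, 0.0852 for ERBB2 (6 cases), 0.0732 for HEXIM1 (4 cases) and 0.0653 for PMAIP1 (4 cases). Without the low count filter, ACLY in HCC1954 against BT474 (0.0593), BCL2 in SKOV3 against BT474 (0.0877), and CDKN1A (0.0510), ERBB2 (0.0767) and HEXIM1 (0.105) in SKOV3 against HCC1954 did not pass; the causes were not tested. Depth limits genes such as BCL2 in HCC1954 (0.259 CPM). Directions of named genes that passed did not change.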

Other observations

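The comparison of gene lists within lines, which describes their spread and tests no cause, was written down before its result was seen; the scan of windows of genes was not.

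Some of the largest differences between lines lay in stretches of neighbouring genes. On chromosome 15 from 22867052 to 29570723, 20 tested genes had a median log2 difference of -7.35 between HCC1954 and BT474, and 5.79 between SKOV3 and HCC1954. This stretch holds the imprinted SNRPN locus: SNRPN had 34.6 CPM in BT474, 0.0110 in HCC1954 and 48.5 in SKOV3, while UBE3A, at the end of the same locus, had 189.6, 157 and 105. Many of the 20 are overlapping transcripts of a single locus, so they are not independent. On chromosome 9 from 2720469 to 6015625 the median was 4.31 in HCC1954 against BT474. There JAK2, a kinase gene of cytokine signalling, had 0.569 CPM in BT474, 57.2 in HCC1954 and 7.09 in SKOV3, and CD274, which encodes PD-L1, had 0.0699, 11.3 and 0.131. On chromosome 8 from 10764963 to 17224799 the median was 6.98 in SKOV3 against HCC1954 and 4.06 against BT474, with the tumour suppressor gene DLC1 at 1.88, 0.0643 and 104 CPM in the order BT474, HCC1954 and SKOV3, and TUSC3 at 0.869, 0.120 and 155. On chromosome 20 from 34280268 to 35412141 the median was -3.18 in HCC1954 against BT474; this stretch holds ACSS2 of the fatty acid synthesis list beside ITCH (551 CPM in BT474 and 82.9 in HCC1954) and TRPC4AP (846 and 82.8).

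Stretches picked by the scan also held developmental gene clusters. Each median below covers all 20 genes of a stretch, including genes outside the cluster, such as CYCS and CBX3 beside the HOXA genes. Developmental genes were not tested as a group. Stretches with HOXA genes had a median log2 difference of 3.58 in HCC1954 and 4.21 in SKOV3 against BT474. Those with HOXC genes had -5.29 in SKOV3 against BT474 and -4.49 against HCC1954, and those with HOXB genes 4.84 in SKOV3 against BT474. A stretch with the protocadherin cluster on chromosome 5 had 4.94 in SKOV3 against BT474 and 5.31 against HCC1954. A stretch with the skin barrier genes S100A7 to S100A11 on chromosome 1 had -4.85 in SKOV3 against HCC1954. Another with HLA class II genes beside others such as NOTCH4 on chromosome 6 had 2.98 in HCC1954 against BT474. Between BT474 and HCC1954, 150 of 15468 overlapping windows of 20 genes passed the highest absolute median of 100 shuffles, as did 151 and 218 in the other comparisons.

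Within lines, some gene lists varied more between libraries than others. Of the 29 lists, 7 had a median within-line SD above a Bonferroni threshold from 10000 random lists of like expression. The random genes were drawn independently, while genes of a fixed list can move together. The estimated correlation was 0.936 for mitochondrially encoded genes, 0.800 for histone genes and 0.713 for DNA replication. The median of such a list varies more than that of a random list, so the threshold is too lenient and the 7 lists are a description only. They were histone genes (SD 1.10 on the log2 scale against 0.369 for random lists), DNA replication (0.592 against 0.304), interferon response (0.834), autophagy and lysosome (0.447 against 0.297), basal markers (0.867 against 0.365), epithelial markers (0.543 against 0.328) and mitochondrially encoded genes (0.723 against 0.289). Deviations of libraries with the same number went together across lines for histone genes (median correlation 0.917), DNA replication (0.820), autophagy and lysosome (0.815), interferon (0.713) and mitochondrially encoded genes (0.644), and not for basal (-0.126) and epithelial markers (-0.0435). Over all tested genes the median SD was 0.413 and the median correlation 0.272.

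Single genes varied widely between libraries; IDO1 and HIST1H3H were picked for their spread. IDO1, an interferon-induced enzyme gene, had 159, 158, 11.4 and 12.4 CPM in libraries 1 to 4 of SKOV3. The histone gene HIST1H3H had 4.00, 3.43, 94.1 and 98.7 CPM in BT474, 8.20, 8.23, 166 and 144 in HCC1954, and 3.31, 2.06, 14.2 and 12.1 in SKOV3. BRD2 had 197, 207, 756 and 779 CPM in BT474, 218, 224, 599 and 614 in HCC1954 and 199, 214, 699 and 708 in SKOV3. SREBF1 had 208, 186, 376 and 411 CPM in BT474, 203, 223, 272 and 253 in HCC1954 and 35.97, 29.2, 17.6 and 17.4 in SKOV3, so libraries 3 and 4 were higher in BT474 and HCC1954 and lower in SKOV3. BCL2 had 22.8, 29.9, 5.12 and 4.09 CPM in BT474, 0.441, 0.297, 0.253 and 0.0467 in HCC1954 and 6.84, 6.68, 1.89 and 2.67 in SKOV3. PMAIP1 had 13.1, 13.1, 7.23 and 7.46 CPM in BT474, 15.9, 14.6, 24.9 and 26.4 in HCC1954 and 27.8, 29.2, 46.3 and 47.2 in SKOV3, with libraries 3 and 4 lower in BT474 and higher in the other lines. These values are given per library only, since the labels name a single treatment.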
